A study of Mus musculus with 8 samples.

How the data were processed

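RNA sequencing was done on 8 libraries of mouse embryonic fibroblasts (C57BL/6) transduced with GHMT retroviruses and treated for 7 days, 2 libraries for each of ethanol (0.1%), DMSO (1%), I-CBP112 (5 µM) and C646 (5 µM), with medium changed every few days. RNA was taken with a column kit and made into TruSeq libraries from total RNA. Groups come from the treatment in the labels. The library numbers 2 and 3 recur in each group, and whether same-numbered libraries were made together is not given in the sources used here. The solvent of each inhibitor is not given there either.

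Per the labels, the authors quantified reads with kallisto 0.43.1 against GRCm38.p5 and tested genes with DESeq2, whose version is not given in the sources used here. The 3 files are the authors' comparison tables, with 50600 genes each and no values of single libraries. In them the signal, baseMean, is the authors' mean normalized count over all 8 libraries, equal in the 3 tables for all 50600 genes, so 1 fit lies behind them. The log2 fold change is the authors' own, without shrinkage, and comes with the authors' standard error. The deposited Wald statistic is a score equal to the fold change over its standard error, to within 3.37e-07. Each p-value and adjusted p (Benjamini-Hochberg) in the tables is the authors' DESeq2 value and is printed as theirs. Adjusted values are given for 14830 genes, with a mean normalized count of 26.1 or more, in the DMSO and I-CBP112 tables and for all 34250 genes with counts in the C646 table.

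The tables name no reference. Ethanol was taken as the reference because it is the group without a table. That a group other than the 3 named is the reference, though not which treatment it had, was checked on genes with few counts. These had a mean normalized count under 0.16, about 1 count in all or less. Of 2312 such genes, 2306 were seen in 1 group only: 550 in DMSO, 536 in I-CBP112, 622 in C646 and 598 in the reference, and 0 showed the opposite sign in any group. The 2 most frequent separate values in each group were taken as steps of a single count and gave size factors from 0.888 to 1.14. Not all of these genes lay on the steps. Multiplied by the sum of baseMean, about 38000000, they estimate library totals from about 33800000 to 43300000 counts; which step belongs to which library is not known. Precision is given by the authors' standard errors, with a median of 0.185 on the log2 scale.

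Gene symbols are the authors'. Gene types and positions come from GENCODE M21, which holds 50376 of the 50600 identifiers when versions are ignored, 14807 of the tested ones. Group means were rebuilt from baseMean and the 3 fold changes. Changed genes against ethanol are those with the authors' adjusted p below 0.05; no test of these was run here. The design fixed before the data were examined gave no value for comparisons between treatments from such tables. They were added after seeing the data: for each pair the difference of the fold changes was divided by a standard error rebuilt from the 3 deposited ones, with 1 dispersion per gene and 4 groups of 2 libraries, and the normal p was adjusted by Benjamini-Hochberg over the 14830 genes. The same formula gave 98.9%, 99.0% and 99.0% of the deposited standard errors of the DMSO, I-CBP112 and C646 tables to within 1%. An upper bound, the root of the summed squares of both standard errors, was kept as an alternative.

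The 29 gene lists were written before the data were examined: reprogramming factors, other cardiac transcription factors, cardiac sarcomere, cardiac calcium handling and ion channels, natriuretic peptides and secreted cardiac markers, skeletal muscle, smooth muscle, fibroblast and extracellular matrix, TGF-beta response, cell cycle, p53 and growth arrest, interferon response, inflammatory cytokines and NF-kappa-B targets, NRF2 and xenobiotic response, integrated stress response, cholesterol synthesis, oxidative phosphorylation, fatty acid oxidation and cardiac metabolism, glycolysis and hypoxia, Wnt, Notch and BMP targets, acetyltransferases and bromodomain proteins, histone deacetylases, endothelial cell, macrophage and leukocyte, neuron and glia, adipocyte, chondrocyte and osteoblast, epithelial and epicardial, and mitochondrially encoded genes. Members with an adjusted p in the DMSO table were counted as measured. Each list was tested with cameraPR (limma 3.58.1) on the Wald statistics, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison; preset values of 0.05 and 0.1 and a test on ranks were added after seeing the data. Similarity between treatments was set beside 100 simulations of unchanged groups with a common reference.

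The rule for named genes took, per comparison with ethanol, the 4 reprogramming factors, Crebbp and Ep300; the 8 genes with the highest and the 8 with the lowest fold change among those past adjusted p 0.05 with a mean normalized count of 50 or more and an informative symbol; and per list up to 3 members past the threshold with the lowest p. Direct comparisons took 5 genes in each direction. The condition on both same-numbered pairs could not be applied. The list rule often names more genes than the text, which gives examples.

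Alternatives tried were a stricter adjusted p of 0.01, a 2-fold minimum, adjustment over all genes with counts, scaling to the totals of the rebuilt means, centring on the median gene, protein-coding genes only, a t distribution with 4 degrees of freedom, a test against a 1.2-fold change, and for C646 statistics divided by their robust standard deviation (SD). Fits to counts with other tools or normalizations, a replicate term and leaving out a library need values per library and were not run.

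The procedure was tested on simulated data with 14830 genes drawn independently. Their standard errors were computed from the true dispersions, so the error of estimating these from 2 libraries per group is not covered. The simulation did not run DESeq2, which gave the calls against ethanol. Of genes changed by 1 on the log2 scale, 67% were recovered for DMSO against ethanol and 78% for I-CBP112 against DMSO, and of those changed by 2, 96% and 96.4%. False calls were 13 of 176 and 18 of 365. With C646 unchanged, 2 genes were called. Of 100 simulated lists of 30 genes without a shift 3 fell below a camera p of 0.05, and of 100 shifted by 1 in the statistic 100 did. Computations used Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3. The values of some single genes are not reported here.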

Results

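RNA sequencing measured transcript levels in C57BL/6 mouse embryonic fibroblasts that carried retroviruses for Gata4, Hand2, Mef2c and Tbx5, the GHMT factors of direct cardiac reprogramming, in which fibroblasts are turned towards heart muscle cells. The cells were kept for 7 days in 0.1% ethanol, in 1% DMSO, in 5 µM I-CBP112, which binds the bromodomains of the acetyltransferases CBP and p300, or in 5 µM C646, which inhibits their acetyltransferase activity. Each treatment had 2 libraries, 8 in all. The values come from 3 tables of the authors' own comparisons, of DMSO, I-CBP112 and C646 each with the same reference, which is read here as ethanol. Each table lists 50600 genes, and 34250 of these have a mean normalised count above 0. Library totals estimated from genes with a single count ran from about 33800000 to 43300000 counts. Mitochondrial ribosomal RNA took 11.4% of the normalised counts, by group 10.5% with ethanol, 12.7% with DMSO, 11.9% with I-CBP112 and 10.6% with C646. For 7SL RNA, of the signal recognition particle, it was 6.81%, by group 7.36%, 7.17%, 5.72% and 6.97%. Errors after ± are the standard errors (SE) of the tables, over groups of 2 libraries; their median over tested genes was 0.185 on the log2 scale. Genes placed in order of fold change below are those past the test with a mean normalised count of 50 or more and an informative symbol. Positions are on GRCm38.

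The first comparison, of DMSO with ethanol, asks what the solvent DMSO does to gene expression during reprogramming. Cells in DMSO had more RNA of heart muscle genes, of cholesterol synthesis and of oxidative phosphorylation. They had less of extracellular matrix, smooth muscle and interferon response genes and of a list of Wnt, Notch and BMP pathway genes. By the adjusted p of the authors' deposited table, 2368 of 14830 tested genes changed, 1197 upward and 1171 downward, and 686 changed at least 2-fold, 237 upward and 449 downward. The balance depends on the scaling, with 1055 upward and 1223 downward scaled to totals and 972 and 1283 centred on the median gene, both chosen after seeing the data. Myl1 (ENSMUSG00000061816.15, chromosome 1, 66924295 to 66945404, minus strand), an essential myosin light chain, was 28.4 times as high as with ethanol in the authors' deposited table, a log2 fold change of 4.83 ± 0.13 (adjusted p = 9.53e-292). Next in that direction in the authors' deposited table were the Z-disc protein Actn2 at 2.83 ± 0.14, the transporters Slc1a2 at 2.81 ± 0.41 and Slc24a2 at 2.81 ± 0.24, and sarcolipin (Sln), a regulator of the sarcoplasmic calcium pump, at 2.78 ± 0.30. Nptx2 at 2.70 ± 0.36, Cited1, a CBP/p300-binding protein, at 2.64 ± 0.22, and Pnma2 at 2.55 ± 0.43 completed the 8 named upward in the authors' deposited table. Downward, Insc (chromosome 7, 114743694 to 114850383, plus strand) fell by 4.13 ± 0.36 (adjusted p = 2.33e-27), to a level 17.5 times lower in the authors' deposited table. Behind it in the authors' deposited table came the microfibril protein Mfap4 at -3.29 ± 0.17, Serpinb9b at -3.29 ± 0.21, the lipid transporter Mfsd2a at -3.27 ± 0.35 and the collagen Col28a1 at -3.09 ± 0.16. The water channel Aqp1 at -3.04 ± 0.16, the cartilage proteoglycan Epyc at -3.04 ± 0.32 and the decoy receptor Tnfrsf11b at -3.02 ± 0.35 followed in the authors' deposited table.

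Heart muscle genes moved upward as groups with DMSO. Of 27 measured cardiac sarcomere genes, 13 rose and 1 fell (adjusted over the list alone, 15 rose and 1 fell), with a median log2 fold change of 0.86 (camera adjusted p = 5.4e-24). Among them the authors' deposited table has Tnni3, cardiac troponin I, at 2.01 ± 0.14 and Myl7, the atrial myosin regulatory light chain, at 2.09 ± 0.11, both higher. The cardiac calcium handling and ion channel list had 9 of 25 members higher and 1 lower (adjusted over the list alone, 10 and 3), with a median of 0.32 (camera adjusted p = 1.5e-05). Its examples in the authors' deposited table are the sodium-calcium exchanger Slc8a1 at 1.40 ± 0.11 and the ryanodine receptor Ryr2, the calcium release channel, at 1.25 ± 0.12. Of the 4 reprogramming factors, 3 rose, also adjusted over the list alone (camera adjusted p = 0.0024), in counts that do not part vector RNA from the RNA of the cells' own genes. Their log2 fold changes in the authors' deposited table were 0.44 ± 0.12 for Gata4, 0.48 ± 0.12 for Hand2 and 0.76 ± 0.13 for Mef2c, with Tbx5 at 0.48 ± 0.35, not past the test. Other cardiac transcription factors had 5 of 14 members higher and 1 lower (adjusted over the list alone, 6 and 1; camera adjusted p = 0.016, and adjusted p = 0.12 with a preset correlation of 0.1). They included Myocd, myocardin, at 1.06 ± 0.17, Tbx2 at 1.03 ± 0.24 and Hopx at 1.03 ± 0.23 in the authors' deposited table. Of 6 natriuretic peptide and secreted cardiac genes 1 rose (adjusted over the list alone, 3; camera adjusted p = 0.18), Ankrd1 at 0.78 ± 0.12 in the authors' deposited table. The skeletal muscle list went both ways, with 3 of 10 members higher and 4 lower, also adjusted over the list alone. Its median was 0.14 with a camera adjusted p of 0.0003 for a rise, while a test on ranks gave an adjusted p of 0.90 in the downward direction. Myl1 and the skeletal actin Acta1 (1.72 ± 0.33) rose and the fast troponin Tnnt3 (-2.67 ± 0.45) fell in the authors' deposited table.

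Fibroblast and other mesenchymal genes moved the other way with DMSO. Of 39 fibroblast and extracellular matrix genes, 24 fell and 0 rose (adjusted over the list alone, 26 fell), with a median of -0.46 (camera adjusted p = 9.8e-20). Elastin (Eln) stood at -2.12 ± 0.12, periostin (Postn) at -0.99 ± 0.12 and the metalloproteinase inhibitor Timp1 at -0.94 ± 0.12 in the authors' deposited table. The smooth muscle list had 11 of 15 members lower and 1 higher, also adjusted over the list alone, with a median of -0.61 (camera adjusted p = 6.8e-11). Examples in the authors' deposited table are Tpm2, a tropomyosin, at -1.87 ± 0.12, Actg2, enteric smooth muscle actin, at -2.30 ± 0.20 and Tagln, transgelin, at -1.08 ± 0.13. Wnt, Notch and BMP targets had 12 of 24 members lower and 1 higher (adjusted over the list alone, 14 and 3), with a median of -0.61 (camera adjusted p = 2.4e-07). The BMP antagonist Grem1 at -1.91 ± 0.16 and the Wnt antagonist Sfrp1 at -1.13 ± 0.15 led that list in the authors' deposited table. Besides targets the list holds ligands, receptors and secreted antagonists of these pathways, so it does not measure their output alone. TGF-beta response genes had 5 of 19 members lower (adjusted over the list alone, 5 lower and 1 higher; camera adjusted p = 0.0017, and adjusted p = 0.055 with a preset correlation of 0.1), among them the activin subunit Inhba at -1.77 ± 0.19 in the authors' deposited table. Markers of other cell types fell in part. Chondrocyte and osteoblast markers had 7 of 13 members lower, also adjusted over the list alone, with a median of -0.72 (camera adjusted p = 6.6e-05), and adipocyte markers had 5 of 10 lower (adjusted over the list alone, 7) with a median of -0.81 (camera adjusted p = 0.0018). Endothelial markers had 2 of 7 lower (adjusted over the list alone, 3; camera adjusted p = 0.0038). Epithelial and epicardial markers had 5 of 9 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0505, not past the threshold), with keratin Krt14 at -3.38 ± 0.72 in the authors' deposited table. Neuron and glia markers had 2 of 6 lower, also adjusted over the list alone (camera adjusted p = 0.040, and adjusted p = 0.12 with a preset correlation of 0.1).

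Antiviral and inflammatory genes were lower with DMSO and several metabolic groups were higher. In the interferon response list 20 of 30 members fell and 0 rose (adjusted over the list alone, 22 fell), with a median of -0.71 (camera adjusted p = 2.8e-14). They included the antiviral synthetases Oas2 at -1.71 ± 0.23 and Oas1a at -1.13 ± 0.17 and the transcription factor Irf7 at -0.94 ± 0.14 in the authors' deposited table. Beside it, 1 of 17 macrophage and leukocyte markers fell, also adjusted over the list alone, with a list median of -0.10 (camera adjusted p = 0.46). Inflammatory cytokines and NF-kappa-B targets had 9 of 20 members lower and 2 higher (adjusted over the list alone, 10 and 3; camera adjusted p = 0.0024, and adjusted p = 0.069 with a preset correlation of 0.1). Stromelysin (Mmp3) was at -1.43 ± 0.20 and complement C3 at -0.93 ± 0.18, whereas the chemokine Ccl2 was at 1.15 ± 0.23 in the authors' deposited table. In the cholesterol synthesis list 15 of 24 members rose and 0 fell (adjusted over the list alone, 16 rose), with a median of 0.51 (camera adjusted p = 1.5e-09), led by Msmo1 at 1.06 ± 0.13 in the authors' deposited table. Oxidative phosphorylation genes had 10 of 46 members higher and 0 lower (adjusted over the list alone, 14 higher), with a median of 0.28 (camera adjusted p = 5.6e-06). Fatty acid oxidation and cardiac metabolism had 8 of 27 higher and 1 lower (adjusted over the list alone, 10 and 1; camera adjusted p = 0.0076, and adjusted p = 0.15 with a preset correlation of 0.1). Glycolysis and hypoxia genes had 7 of 25 higher and 2 lower (adjusted over the list alone, 10 and 2; camera adjusted p = 0.018, and adjusted p = 0.18 with a preset correlation of 0.1); the hexokinases parted, with Hk1 at 0.69 ± 0.13 and Hk2 at -1.40 ± 0.24 in the authors' deposited table. Integrated stress response genes had 5 of 25 lower and 1 higher (adjusted over the list alone, 6 and 1; camera adjusted p = 0.021, and adjusted p = 0.19 with a preset correlation of 0.1), among them the kinase-like Trib3 at -1.09 ± 0.18 in the authors' deposited table.

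The cell cycle, p53, NRF2, acetyltransferase, histone deacetylase and mitochondrially encoded lists did not pass the camera test with DMSO. Of 40 cell cycle genes 1 rose and 2 fell, also adjusted over the list alone, with a median of 0.05 (camera adjusted p = 0.78). The p53 and growth arrest list had 3 of 16 members lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.25), and the cell cycle inhibitor Cdkn1a was at -1.21 ± 0.16 in the authors' deposited table. Of 24 NRF2 and xenobiotic response genes 4 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.097). Of 32 acetyltransferases and bromodomain proteins 2 rose (adjusted over the list alone, 1; camera adjusted p = 0.58). Crebbp at 0.01 ± 0.21 and Ep300 at 0.03 ± 0.15, which encode CBP and p300, were not past the test in the authors' deposited table. Of 18 histone deacetylases 3 rose, also adjusted over the list alone (camera adjusted p = 0.16), with Hdac9 at 1.75 ± 0.21 in the authors' deposited table. Of 13 mitochondrially encoded genes 1 rose, also adjusted over the list alone (camera adjusted p = 0.62). The plot of gene list medians sets these groups beside those of the other treatments. With 2 libraries per group the calls rest on a spread pooled over genes: 1 gene passed with a t distribution of 4 degrees of freedom in place of the normal distribution, an alternative chosen after seeing the data. Of the 20 lists past the camera threshold, 13 stayed past it with a preset correlation of 0.1; a correlation could not be estimated without values per library.

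**Figure D1:**
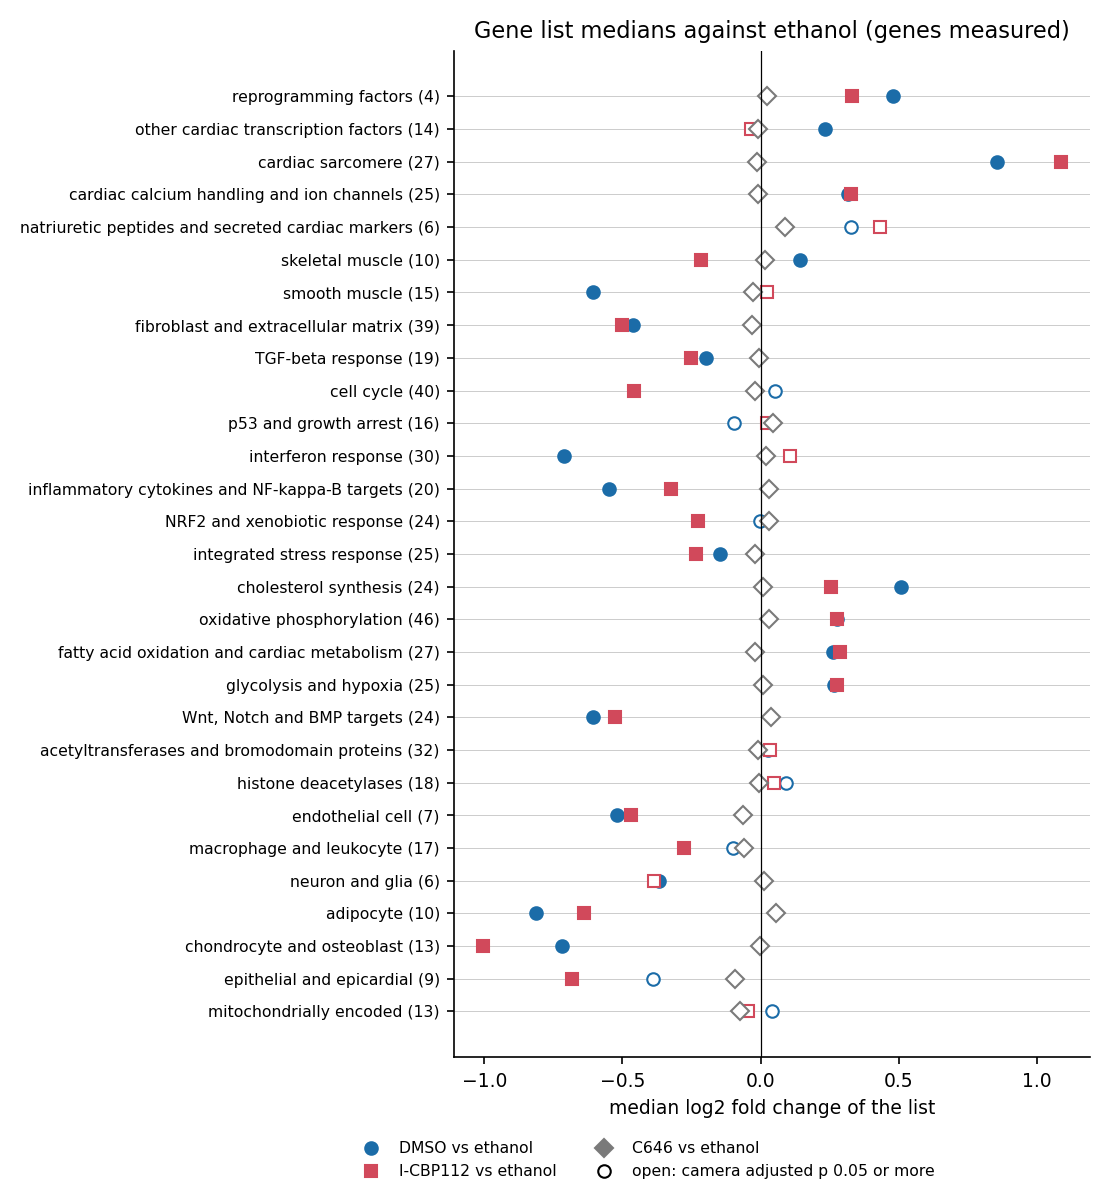
Median log2 fold change against ethanol (horizontal axis) of the 29 gene lists (vertical axis, number of measured genes in parentheses) with DMSO (circles), I-CBP112 (squares) and C646 (diamonds); open symbols mark a camera adjusted p of 0.05 or more. The cardiac sarcomere medians are 0.86 with DMSO and 1.09 with I-CBP112, the interferon response medians are -0.71 and 0.11, and all 29 C646 symbols are open and lie near 0.

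The second comparison, of I-CBP112 with ethanol, asks what binding the CBP/p300 bromodomains does to the same cells. Its solvent is not given in the sources used here, so a solvent effect cannot be told apart from that of I-CBP112. I-CBP112 also went with more RNA of heart muscle genes and less of fibroblast matrix genes. By the adjusted p of the authors' deposited table, 1468 of 14830 tested genes changed, 689 upward and 779 downward, and 423 changed at least 2-fold, 161 upward and 262 downward. Scaled to totals it was 754 upward and 720 downward, and centred on the median gene 633 and 821, so which direction had more genes depends on the scaling. Nppa (ENSMUSG00000041616.9, chromosome 4, 148000722 to 148002079, plus strand), atrial natriuretic peptide, was 16.2 times as high in the authors' deposited table, at a log2 fold change of 4.02 with the wide error of ± 1.29 (adjusted p = 0.0239). With DMSO the Nppa value in the authors' deposited table was 3.15 ± 1.29, not past the test. Otogl followed at 2.99 ± 0.46, then Myl1 at 2.91 ± 0.13, Sln at 2.79 ± 0.30 and the carbonic anhydrase-related Car8 at 2.20 ± 0.45 in the authors' deposited table. Actn2 at 2.18 ± 0.14, the heavy chain Myh6 of cardiac myosin at 2.18 ± 0.16 and Cyfip2 at 2.01 ± 0.40 completed the 8 upward in the authors' deposited table. Insc again fell furthest of the named genes, by 4.10 ± 0.34 (adjusted p = 6.7e-31), in the authors' deposited table. The forkhead factor Foxs1 at -3.05 ± 0.48, Epyc at -2.78 ± 0.32, Plb1 at -2.70 ± 0.56 and Mfap4 at -2.64 ± 0.16 came next in the authors' deposited table. Tenomodulin (Tnmd), a tendon protein, at -2.62 ± 0.27, Aqp1 at -2.59 ± 0.16 and Mfsd2a at -2.56 ± 0.33 were the others named downward in the authors' deposited table.

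Of 27 cardiac sarcomere genes 19 rose and 1 fell with I-CBP112, also adjusted over the list alone, with a median of 1.09 (camera adjusted p = 1.3e-46). The giant elastic protein Ttn, titin, was at 1.93 ± 0.17 and Tnni3 at 1.65 ± 0.15 in the authors' deposited table. Calcium handling and ion channel genes had 8 of 25 members higher and 2 lower (adjusted over the list alone, 8 and 3), with a median of 0.33 (camera adjusted p = 3.2e-05), among them Slc8a1 at 1.22 ± 0.11 and Ryr2 at 1.00 ± 0.12 in the authors' deposited table. Of the 4 reprogramming factors 3 rose, also adjusted over the list alone (camera adjusted p = 0.012): Gata4 at 0.33 ± 0.12, Hand2 at 0.32 ± 0.12 and Mef2c at 0.50 ± 0.13 in the authors' deposited table. Tbx5 at 0.30 ± 0.35, Crebbp at 0.06 ± 0.21 and Ep300 at -0.10 ± 0.15 were not past the test in the authors' deposited table. Of 14 other cardiac transcription factors 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.78), with Prox1 at 1.52 ± 0.42 and Tbx20 at -0.59 ± 0.17 in the authors' deposited table. Natriuretic peptide and secreted cardiac genes had 2 of 6 members higher (adjusted over the list alone, 3 higher and 2 lower; camera adjusted p = 0.12). The skeletal muscle list had 2 of 10 members higher and 1 lower (adjusted over the list alone, 2 and 3), with a median of -0.22, a mean of 0.09 and a camera adjusted p of 0.025 for a rise, which became an adjusted p of 0.10 with a preset correlation of 0.1. The smooth muscle list had 2 of 15 members higher and 1 lower, also adjusted over the list alone, with a median of 0.02 (camera adjusted p = 0.69).

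Of 39 fibroblast and extracellular matrix genes 24 fell and 1 rose with I-CBP112 (adjusted over the list alone, 28 and 2), with a median of -0.50 (camera adjusted p = 3.6e-28). The microfibril protein Mfap5 was at -1.96 ± 0.19, Eln at -1.38 ± 0.12 and the collagen Col1a2 at -0.93 ± 0.12 in the authors' deposited table. Wnt, Notch and BMP targets had 11 of 24 members lower and 1 higher (adjusted over the list alone, 14 and 2; median -0.53; camera adjusted p = 7.3e-11), led by the Wnt antagonist Dkk2 at -1.89 ± 0.15 in the authors' deposited table. TGF-beta response genes had 3 of 19 lower (adjusted over the list alone, 6; camera adjusted p = 0.00085). Chondrocyte and osteoblast markers had 7 of 13 lower and 1 higher (adjusted over the list alone, 10 and 1; mean -0.89; camera adjusted p = 1.4e-06), and epithelial and epicardial markers had 6 of 9 lower (adjusted over the list alone, 7; median -0.68; camera adjusted p = 0.00011). Endothelial markers had 3 of 7 lower (adjusted over the list alone, 4; camera adjusted p = 0.0016). Adipocyte markers had 3 of 10 lower (adjusted over the list alone, 4; camera adjusted p = 0.014, and adjusted p = 0.077 with a preset correlation of 0.1). Macrophage and leukocyte markers had 3 of 17 lower, also adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.044, and adjusted p = 0.21 with a preset correlation of 0.1): Csf1r at -0.64 ± 0.22, Adgre1 at -0.74 ± 0.24 and Cx3cr1 at -2.03 ± 0.72 in the authors' deposited table. Of 6 neuron and glia markers 0 passed the test (DESeq2; 4 had an unadjusted p below 0.05; adjusted over the list alone, 2 rose; camera adjusted p = 0.87).

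In the cell cycle list 8 of 40 members fell and 1 rose with I-CBP112 (adjusted over the list alone, 11 and 1), with a median of -0.46 (camera adjusted p = 0.00011, and adjusted p = 0.057 with a preset correlation of 0.1). The spindle factor Tpx2 was at -0.73 ± 0.20 and the ribonucleotide reductase subunit Rrm2 at -0.80 ± 0.17, whereas the centromere histone Cenpa was at 0.75 ± 0.15 in the authors' deposited table. Oxidative phosphorylation genes had 11 of 46 members higher and 0 lower (adjusted over the list alone, 16 higher; median 0.28; camera adjusted p = 1.2e-09). Fatty acid oxidation and cardiac metabolism had 8 of 27 higher and 1 lower (adjusted over the list alone, 9 and 1; median 0.29; camera adjusted p = 1.9e-05), among them the heart fatty acid binding protein Fabp3 at 1.02 ± 0.19 in the authors' deposited table. Cholesterol synthesis genes had 7 of 24 higher and 0 lower (adjusted over the list alone, 10 higher; median 0.25; camera adjusted p = 3.2e-05). Glycolysis and hypoxia genes had 6 of 25 higher and 1 lower (adjusted over the list alone, 9 and 1; camera adjusted p = 0.0012, and adjusted p = 0.066 with a preset correlation of 0.1). Inflammatory cytokines and NF-kappa-B targets had 7 of 20 lower and 2 higher (adjusted over the list alone, 9 and 2; camera adjusted p = 0.00071), with the chemokine Cxcl5 at -2.17 ± 0.37 in the authors' deposited table. NRF2 and xenobiotic response genes had 7 of 24 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.0009, and adjusted p = 0.057 with a preset correlation of 0.1). Integrated stress response genes had 8 of 25 lower (adjusted over the list alone, 9 lower and 1 higher; camera adjusted p = 0.00079, and adjusted p = 0.057 with a preset correlation of 0.1). In the interferon response list 1 of 30 members rose, also adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.23). Of 16 p53 and growth arrest genes 1 rose (camera adjusted p = 0.60), of 18 histone deacetylases 2 rose and 1 fell (camera adjusted p = 0.26) and of 13 mitochondrially encoded genes 1 rose (camera adjusted p = 0.70), with the same counts adjusted over the list alone. Of 32 acetyltransferases and bromodomain proteins 0 changed (DESeq2; 0 also at an unadjusted p below 0.05; camera adjusted p = 0.88). With a t distribution of 4 degrees of freedom, an alternative chosen after seeing the data, 0 genes passed; 13 of the 20 lists past the camera threshold stayed past it with a preset correlation of 0.1.

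The third comparison, of C646 with ethanol, asks what inhibition of the CBP/p300 acetyltransferase activity does. At 5 µM C646 the heart muscle and fibroblast genes that moved with the other treatments stayed close to their ethanol levels. By the adjusted p of the authors' deposited table (DESeq2), 2 of 34250 tested genes changed, and 199 had an unadjusted p below 0.05. Both were looked at after their values were seen. Cacnb4 (chromosome 2, 52428320 to 52676831, minus strand), a subunit of voltage-gated calcium channels, was 3.06 times lower with C646, at a log2 fold change of -1.61 ± 0.27 (adjusted p = 7.38e-05) in the authors' deposited table. Cacnb4 was at -0.11 ± 0.27 with DMSO and -0.49 ± 0.27 with I-CBP112, neither past the test, in the authors' deposited table. Gm37167, a gene without a known product, stood at 8.39 ± 1.68 (adjusted p = 0.0098) in the authors' deposited table, where its mean normalised count is 14.5. Its log2 fold change is exactly 0 with DMSO and with I-CBP112 in the authors' deposited table, which goes with no counts in these groups and in ethanol, so the size of its fold with C646 is not a measured one. In all 29 gene lists 0 members passed the test, also adjusted over the list alone, 4 of their 583 measured genes had an unadjusted p below 0.05 (DESeq2), and the lowest camera adjusted p was 0.51. The cardiac sarcomere median was -0.01, the fibroblast and extracellular matrix median -0.03 and the interferon response median 0.02. Gata4 was at 0.02 ± 0.12, Crebbp at 0.02 ± 0.21 and Ep300 at -0.16 ± 0.15 in the authors' deposited table. The 95% interval of a C646 fold change reached 0.362 on the log2 scale to either side at the median gene. Adjusted over the 14830 genes tested in the other tables, an alternative chosen after seeing the data, 1 gene remained, Cacnb4. With the statistics divided by their robust standard deviation, also chosen after seeing the data, 192 genes passed, 89 higher and 103 lower. A common divisor was used for all genes, although the spread of the statistics depended on the mean count.

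DMSO and I-CBP112 moved many of the same genes in the same direction. Whether I-CBP112 was given in DMSO is not stated in the sources used here, so a solvent effect in both cannot be told apart. Of the genes changed by both in the authors' deposited table, 417 rose with both, 477 fell with both and 14 went opposite ways. If the calls were independent, 55.6 and 61.5 shared genes would be the number upward and downward; calls against a common reference are not independent. Across 14830 genes, which are not independent replicates, the DMSO and I-CBP112 fold changes had a Pearson r of 0.644 and a Spearman rho of 0.591. A common reference alone gave r of 0.495 and rho of 0.461 in simulation, and the covariance was 0.150 against a simulated 0.0482. Between comparisons that share no libraries, chosen after seeing the data, r was 0.516 for DMSO minus C646 with I-CBP112 minus ethanol and 0.539 for DMSO minus ethanol with I-CBP112 minus C646. DMSO and C646 fold changes had r of 0.175, below the simulated 0.498, and I-CBP112 and C646 fold changes had r of 0.248, below the simulated 0.50. These were 3 correlations in 1 family, given without p because genes are not independent. Over the 894 genes that moved the same way with DMSO and I-CBP112, the median size of the log2 fold change was 0.868 with DMSO, 0.782 with I-CBP112 and 0.0559 with C646. The genes were selected for passing the test with DMSO and I-CBP112, so part of the contrast with C646 is built in.

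**Figure D2:**
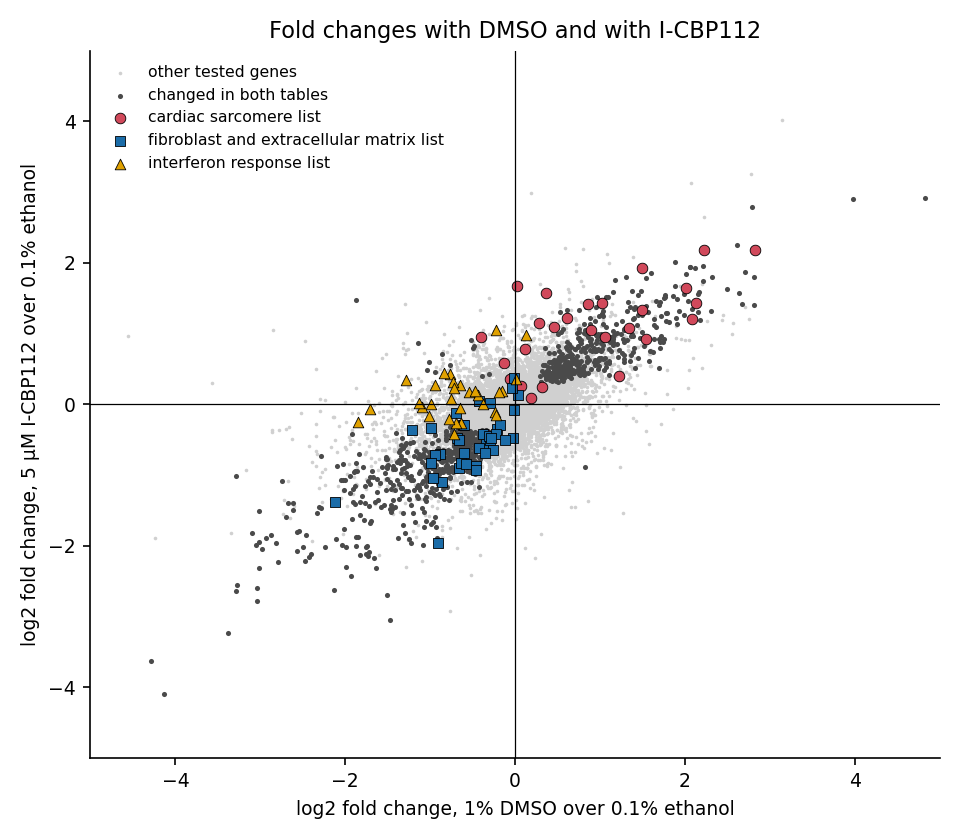
Log2 fold change over ethanol with DMSO (horizontal axis) and with I-CBP112 (vertical axis) of 14830 tested genes, 1 of which lies outside the axes; dark points are genes changed in both tables, and large symbols mark 3 gene lists. Sarcomere genes lie mostly at upper right, fibroblast and matrix genes at lower left, and interferon response genes lie left of 0 near the horizontal line, with medians of -0.71 for DMSO and 0.11 for I-CBP112.

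The direct comparison of I-CBP112 with DMSO tests whether the changes seen with these treatments differ. It was computed after the data were seen, from the fold changes and a standard error rebuilt from the 3 tables. Interferon response and smooth muscle genes were higher with I-CBP112 than with DMSO. Of 14830 tested genes 1034 differed at an adjusted p below 0.05, 639 higher and 395 lower with I-CBP112; 198 and 79 of them differed at least 2-fold. Ptgds, prostaglandin D2 synthase, was highest above DMSO, by 3.35 ± 0.51 on the log2 scale (adjusted p = 7.14e-09), followed by the lipid droplet protein Plin4 at 2.84 ± 0.38, Otogl at 2.80 ± 0.46, the interferon-induced GTPase Tgtp2 at 2.49 ± 0.53 and Aspg at 2.47 ± 0.57. Among the lowest were Tinag at -2.12 ± 0.57, the calcium channel gene Cacna1b at -1.93 ± 0.43, Myl1 at -1.91 ± 0.13 (adjusted p = 5.71e-47) and the amino acid transporter Slc43a2 at -1.78 ± 0.25. In the interferon response list 21 of 30 members were higher and 0 lower (adjusted over the list alone, 25 higher), with a median difference of 0.84 (camera adjusted p = 2.8e-33); Irf7 differed by 1.21 ± 0.14 and Oas2 by 1.65 ± 0.23. Smooth muscle genes had 8 of 15 members higher and 0 lower (adjusted over the list alone, 9 higher), with a median of 0.41 (camera adjusted p = 8.8e-22); Tpm2 differed by 2.10 ± 0.12 and Actg2 by 2.21 ± 0.20. These 2 lists stayed past the threshold with a preset correlation of 0.1.

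The remaining 6 lists past the camera threshold lost it with that correlation. Cell cycle genes had 9 of 40 members lower with I-CBP112 (adjusted over the list alone, 14 lower and 2 higher), with a median of -0.59 (camera adjusted p = 4.5e-06, and adjusted p = 0.070 with a preset correlation of 0.1); Tpx2 differed by -1.21 ± 0.20. Cholesterol synthesis genes had 5 of 24 lower (adjusted over the list alone, 6; camera adjusted p = 0.00295, and adjusted p = 0.15 with a preset correlation of 0.1). Other cardiac transcription factors had 2 of 14 lower, also adjusted over the list alone (camera adjusted p = 0.0094, and adjusted p = 0.15 with a preset correlation of 0.1). Skeletal muscle genes had 2 of 10 higher and 1 lower (adjusted over the list alone, 2 and 2), with a median of -0.20 and a camera adjusted p of 0.036 for a fall, against an adjusted p of 0.19 with a preset correlation of 0.1 and 0.57 on ranks. Neuron and glia markers had 3 of 6 higher, also adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.15 with a preset correlation of 0.1). The p53 list had 2 of 16 members higher and 1 lower (adjusted over the list alone, 3 and 1; camera adjusted p = 0.0499, and adjusted p = 0.34 with a preset correlation of 0.1); Cdkn1a differed by 1.28 ± 0.16. The sarcomere list had 6 of 27 members higher and 3 lower (adjusted over the list alone, 9 and 4; camera adjusted p = 0.084). Its members lower with I-CBP112 than with DMSO included Myl7 at -0.88 ± 0.11 and Actn2 at -0.65 ± 0.14. Myh6 differed by -0.05 ± 0.16, Sln by 0.01 ± 0.29 and the reprogramming factors by -0.11 ± 0.12 for Gata4, -0.16 ± 0.12 for Hand2 and -0.26 ± 0.13 for Mef2c, none past the test. With an upper bound of the standard error 237 genes differed, and with a t distribution of 4 degrees of freedom 0.

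C646 was set against DMSO and against I-CBP112 in the same way. Cells in C646 had less RNA of sarcomere genes and more of fibroblast matrix genes than cells in either. From DMSO, 2349 of 14830 genes differed, 1183 higher and 1166 lower with C646, led by Insc and Serpinb9b upward and by Myl1 and Actn2 downward. The sarcomere list had 16 of 27 members lower with C646 than with DMSO and 1 higher, also adjusted over the list alone (camera adjusted p = 3.2e-25). In that comparison the fibroblast and extracellular matrix list had 21 of 39 higher and 0 lower (adjusted over the list alone, 23 higher; camera adjusted p = 2.7e-17), and the interferon response list 22 of 30 higher and 0 lower (adjusted over the list alone, 24 higher; camera adjusted p = 3.4e-16). I-CBP112 and C646, inhibitors of different domains of the same proteins, were both given at 5 µM for 7 days. Between them 1454 genes differed, 696 higher and 758 lower with I-CBP112, with Nppa, Otogl and Myl1 leading upward and Insc, Plb1 and Foxs1 downward. The sarcomere list had 18 of 27 members higher with I-CBP112 and 1 lower (adjusted over the list alone, 22 and 1), with a median difference of 1.13 (camera adjusted p = 6.1e-49). The fibroblast and extracellular matrix list had 23 of 39 lower and 1 higher (adjusted over the list alone, 27 and 2), with a median of -0.49 (camera adjusted p = 9.2e-25). With the upper bound of the standard error, 839 genes differed between C646 and DMSO and 501 between I-CBP112 and C646; with a t distribution of 4 degrees of freedom it was 0 in both.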

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

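All tests in this part were chosen only after the result was seen.

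For 14 genes the tables gave changes past the threshold in opposite directions with DMSO and I-CBP112. Genes chosen in this way pass the direct test of the difference by construction, so it adds no support. The genes that fell with DMSO and rose with I-CBP112 are listed by the log2 difference of I-CBP112 minus DMSO. Prostaglandin D2 synthase Ptgds differed by 3.35, and the melanocyte gene Mlana by 2.02. The apolipoprotein L genes Apol9a and Apol9b differed by 1.62 and 1.57. Gpnmb, a glycoprotein of lysosomes and melanosomes, differed by 1.52 and the Wnt modulator Dkk3 by 1.44. Myl9, the smooth muscle myosin regulatory light chain, differed by 1.39, the lysosomal nuclease Dnase2a by 1.31 and the chromatin remodeller Smarca1 by 1.30. Osteopontin (Spp1) also differed by 1.30, as did Uap1l1, while the kinase regulators Pkia and Akap2 differed by 0.78 and 0.74. Adamts18 rose with DMSO and fell with I-CBP112, with a difference of -1.71.

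C646 libraries lay close to ethanol, with 2 changed genes, or 192 when the statistics are divided by their robust SD. Errors independent between genes would hide single calls but not shift a list median. The C646 median was -0.0122 (95% interval -0.05 to 0.03) over the cardiac sarcomere list. Over the fibroblast and extracellular matrix list it was -0.0301 (95% interval -0.05 to -0.01). The medians with I-CBP112 were 1.09 and -0.50. This argues against imprecision of single genes hiding changes of that size in these lists. Errors common to the genes of a list, smaller changes and other genes stay open. Standard errors that overstate the spread between these particular libraries may add to the low count. The robust SD of the C646 statistics was 0.516, against 1.62 with DMSO and 1.30 with I-CBP112. For C646 it was 0.626 in the lowest decile of genes by mean count and 0.347 in the highest. The common divisor behind the 192 genes is thus too small for the former and too large for the latter. In simulated unchanged groups the SD was 0.998, but their standard errors held the true dispersions, so that value was built in. The covariance of C646 and DMSO fold changes was 0.464 of its simulated value; a component common to same-numbered libraries and ethanol libraries with less spread than the others cannot be told apart without values per library. Whether 5 µM C646 was active in these cells was not tested.

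Sarcomere genes rose with DMSO and with I-CBP112. Scaling between libraries is argued against only as far as the other scalings reach. Under them the lowest list median in these comparisons was 0.82. They lay close to the scaling in use. Log2 totals differed from ethanol by 0.0191 with DMSO and -0.0210 with I-CBP112, and the median genes by 0.0346 and 0.0150. A scaling error common to all of them would not show. A single difference in the share of reprogrammed cells between these treatments would move sarcomere genes 1 way. Yet 6 were higher (Actc1, Tnni1, Myom2, Myoz2, Synpo2l, Trim63) and 3 lower (Myl7, Actn2, Nebl) with I-CBP112. With the upper bound of the standard error it was 3 higher and 1 lower, too few downward to argue against such a difference. The comparison covers DMSO against I-CBP112 only, not the rise of either over ethanol. More RNA of the retroviral factors stays open: their median log2 fold change with DMSO was 0.48, and vector RNA and the cells' own RNA cannot be told apart because they are counted together. A biological effect of the treatments on reprogramming stays open too, as the design names it. As the solvent of I-CBP112 is not given, an effect of I-CBP112 cannot be told apart from one of its solvent.

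Interferon response genes fell with DMSO and not with I-CBP112, a difference past its own test. The median of the macrophage and leukocyte list with DMSO was -0.10 (95% interval -0.38 to 0.06), above the interferon median of -0.71. This argues against fewer macrophages or other leukocytes, as far as an interval over genes allows. Less retroviral vector RNA as a trigger stays open: the 4 factors had a mean log2 fold change with DMSO of 0.54 (95% interval 0.34 to 0.74), in which vector RNA and the cells' own RNA cannot be told apart because they are counted together. An effect of DMSO on interferon signalling stays open too and was not tested.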

How the results depend on the processing

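Chosen after seeing the data were the direct tests, the upper bound, the t distribution, the 1.2-fold test, the scalings, the protein-coding subset, the robust SD, the other list correlations and ranks, and the comparisons without a common reference. In the order DMSO, I-CBP112, I-CBP112 against DMSO, C646 against DMSO and I-CBP112 against C646, an adjusted p below 0.01 gave 1522, 976, 596, 1526 and 951 genes, and a 2-fold minimum 686, 423, 277, 704 and 424. The test against a 1.2-fold change gave 901, 531, 275, 879 and 522. The t distribution with 4 degrees of freedom gave 1, 0, 0, 0 and 0, and 0 for C646 against ethanol. The upper bound of the standard error gave 237, 839 and 501 for the direct comparisons. C646 against ethanol had 1 gene when adjusted over the genes of the DMSO table, scaled to totals, centred on the median, limited to protein-coding genes or tested against 1.2-fold, and 192 with the robust SD. Adjustment over all genes with counts gave 1885 genes with DMSO and 1166 with I-CBP112. The numbers of genes higher and lower moved with the scaling: in the same order of comparisons, 1197 and 1171, 689 and 779, 639 and 395, 1183 and 1166, and 696 and 758 as reported became 1055 and 1223, 754 and 720, 742 and 308, 1288 and 993, and 726 and 726 scaled to totals, and 972 and 1283, 633 and 821, 717 and 323, 1309 and 963, and 655 and 790 centred on the median. Fewer genes pass stricter thresholds, or adjustment over more genes, by construction; for the other changes the cause was not tested. The DMSO and I-CBP112 r was 0.703 for genes with a mean log2 CPM of 3 or more, and 0.516 and 0.539 without a common reference. With a correlation of 0.1, 13 lists passed with DMSO, 13 with I-CBP112 and 11 for C646 against DMSO; for I-CBP112 against DMSO it was 2, with 3 at a correlation of 0.05 and 5 on ranks. Of 92 gene results named with DMSO, 86 with I-CBP112 and 1 with C646, none reversed, but the settings run on them could hardly reverse a direction. Totals differed from ethanol by only 0.0191, -0.0210 and -0.00882 on the log2 scale. The settings other than scaling to totals left the fold changes as they were. Adjustment over all genes with counts ended 2, 9 and 0 of these calls, scaling to totals 1, 1 and 0, the 1.2-fold test 21, 37 and 0, and the t distribution 91, 86 and 1.

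No paired analysis was possible because the tables hold no values per library. For the same reason the planned edgeR and DESeq2 fits, other normalizations, replicate block, pairwise fits, leaving out of libraries, pseudocounts, estimated correlation and fry were not run. At these depths the 95% interval of a C646 fold change reached 0.362 on the log2 scale to either side at the median gene.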

Other observations

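All gene families, genes and tests in this part were chosen only after the data were seen. Histone genes were higher with DMSO: of 59 measured replication-dependent histone genes 21 rose and 0 fell, with a median log2 fold change of 0.46 (camera adjusted p = 9.5e-07, and adjusted p = 0.042 with a preset correlation of 0.1). Hist1h4c stood at 0.88 ± 0.18 and the linker histone Hist1h1e at 0.60 ± 0.17 in the authors' deposited table. The rise was not limited to this class: of 10 other histone genes 5 rose and 0 fell with DMSO. Their median was 0.35 (camera adjusted p = 0.0090, and adjusted p = 0.084 with a preset correlation of 0.1). With I-CBP112, 2 of the 59 rose and 2 fell, and against DMSO 8 were lower and 0 higher, with a median of -0.44 (camera adjusted p = 1.9e-08). Of 11 genes of MHC class I and class Ib and their partner B2m, whose products present peptides to T cells, 7 fell and 1 rose with DMSO, with a median of -0.55 (camera adjusted p = 0.00058, and adjusted p = 0.039 with a preset correlation of 0.1), and 6 were higher and 0 lower with I-CBP112 than with DMSO. Of 77 ribosomal protein genes 3 fell with DMSO, with a median of -0.17 (camera adjusted p = 0.0038, and adjusted p = 0.24 with a preset correlation of 0.1).

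Vacuolar ATPase genes, whose products acidify lysosomes, were higher with I-CBP112: 10 of 16 rose and 0 fell, with a median of 0.42 (camera adjusted p = 8.6e-11). With DMSO 2 of the 16 rose, with a median of 0.18 (camera adjusted p = 0.039, and adjusted p = 0.24 with a preset correlation of 0.1). In the direct test 2 were higher and 0 lower with I-CBP112 than with DMSO, with a median of 0.26 (camera adjusted p = 1.1e-05). Atp6v1a was at 0.42 ± 0.12 and Atp6v0d1 at 0.44 ± 0.12 with I-CBP112 in the authors' deposited table. The metal-binding metallothioneins rose with both treatments: Mt1 was at 0.61 ± 0.20 with DMSO and 1.33 ± 0.20 with I-CBP112, and Mt2 at 0.75 ± 0.20 and 1.34 ± 0.20, in the authors' deposited table. They were higher with I-CBP112 than with DMSO, Mt1 by 0.72 ± 0.20 and Mt2 by 0.59 ± 0.20. Of 66 small nucleolar RNA genes 2 fell with I-CBP112, with a median of -0.49 (camera adjusted p = 0.00041, and adjusted p = 0.20 with a preset correlation of 0.1). Among other short RNA, 7SL RNA took 5.72% of the rebuilt counts with I-CBP112 and 7.36% with ethanol. The shares of 7SK, RNase MRP and RNase P RNA were 1.47% and 1.77%. These shares come without an error or a test. Whether the libraries differ in short RNA as a whole was not tested. None of these families had a member past the test with C646.

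The histone rise with DMSO, which was not limited to replication-dependent genes, raised the hypothesis of more cells in S phase. The 14 replication genes of the cell cycle list had a median log2 fold change of -0.19 with DMSO. The 95% interval over genes, not libraries, was -0.32 to -0.07, and the camera adjusted p was 0.20. The lack of a rise in these genes argues against the hypothesis, as far as 2 libraries per group allow. The vacuolar ATPase rise raised the hypothesis of a wider rise of lysosomal genes. Of 38 other lysosomal genes 14 rose and 0 fell with I-CBP112, with a median of 0.31 (95% interval 0.25 to 0.40; camera adjusted p = 1.2e-11), so the rise may extend to the lysosome more widely. With DMSO 9 of the 38 rose and 3 fell, with a median of 0.19 (95% interval 0.04 to 0.24; camera adjusted p = 0.065). With I-CBP112 against DMSO 11 were higher and 1 lower, with a median of 0.25 (camera adjusted p = 3.1e-07).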
